A study of Mus musculus with 12 samples.

How the data were processed

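Spleen cells of 4 male mice were measured, 2 WT mice of strain C57BL/6 and 2 SLE.yaa mice of strain B6.Sle1yaa. Cells carrying CD45 were enriched with magnetic beads and captured in 10x Genomics droplets, and each mouse gave 1 expression, 1 B cell receptor and 1 T cell receptor library. The submitters' processing notes name Cell Ranger 5.0.0, Seurat 4.0.0 and the mouse build GRCm38 (mm10). Groups were taken from the labels, where they stand under a tag that mentions chimeras; whether the mice were chimeras is not given in the sources used here. Replicate numbers follow the order of the records and pair no mice. The deposited age was 14.4 in the WT mice and 14.9 in the SLE.yaa mice, with no unit stated, so age differs with the group.

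The deposited expression table holds natural logarithms (ln) of 1 plus a whole number per gene and cell. The whole numbers, within 1.64e-11, are depth-adjusted values that the authors made by a method not given in the sources used here. Their sums per cell span 2663 to 6382, or 2.397-fold, while the UMI counts of the same cells span 1002 to 26847, or 26.8-fold. The plan had expected raw counts, so the tests on expression were changed to those for values that are not counts. The deposited cell table gives UMI and gene counts per cell, the percent of mitochondrial and ribosomal UMIs, and scores for cell cycle and heat shock that the authors computed. Other columns deposited with it name the mouse, the condition and the cell type that the authors annotated. The deposited cells hold at most 2999 genes and at most 5.00% mitochondrial UMIs, and the filters that led to this are the authors'. The deposited heavy-chain table gives UMI and read counts per contig, and the fraction of V bases equal to the germline. Other columns from the authors name segments, CDR3 sequences and clones in both receptor tables.

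The expression table held 22285 cells and 16094 genes after 15 rows without a gene name were left out, which held 0.0440% of the values. In 56 symbols a dot was read as a hyphen, and 15368 symbols were found in the GRCm38.p6 annotation, which gave positions for 172 of 174 named genes. Heavy chains came from 13740 cells, 11339 of them in the expression table, and alpha and beta chains from 4001 cells, 3281 of them in that table. The isotype was missing for 85 heavy chains, and where more than 1 IGHV gene was called (366 chains) the first was used. The T cell receptor table lists the values of 2 chains per cell sorted within each field, so V, J and CDR3 could be assigned to a chain only where they could be told apart. The 3467 cells where this was possible were used and 534 were not, a restriction set after T cell values from a wider set had been seen. TRBV12-2 and TRBV13-2 were not told apart by this and are written TRBV12-2/13-2.

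For each mouse and cell type, the depth-adjusted values were averaged over cells, scaled to a sum of 1000000 (vpm) and scaled between mice with TMM factors. B cells were the types B, B-ISG and B-early, myeloid cells were Mac and DC, and other types needed 20 cells in each mouse. Genes with at least 10 vpm in at least 2 mice were tested with limma (trend, robust variance off) on log2 of the value plus 10, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Calls under 4 scalings had been looked at in an exploratory run before TMM, which the plan named, was kept, and the pseudocount and the minimum of 10 were set after that run. Without scaling, the median log2 change of all genes was 0.16 over all cells, 0.20 in B cells and 0.16 in CD4 T cells. On values scaled to the sum alone it was −0.10 in CD8 T cells, −0.11 in myeloid cells, −0.12 in Mac, −0.14 in neutrophils and −0.11 in NK cells. With TMM it lay within 0.05 of 0 in the 5 main comparisons, and changes are given relative to that.

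A total of 22 gene lists with 277 genes were fixed, and lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over lists. The platelet list and the stromal list had fewer than 3 measured genes in the 5 main comparisons and were not tested as lists. Of their genes, Itgb3 fell (-1.49) and Igfbp7 rose (1.76) in CD4 T cells. The difference between the changes in CD4 and CD8 T cells was tested on the differences within mice. Cell types, isotypes and V genes were tested as counts per mouse with edgeR quasi-likelihood fits with the total of the mouse as library size and, for V genes, at least 10 clones in at least 2 mice (70 of 97 IGHV, 20 of 22 TRBV and 39 of 87 TRAV genes). For cell types, isotypes and TRBV genes, whose tables have few rows, the dispersion was estimated without a trend on abundance. For IGHV and TRAV genes it was estimated with such a trend. This setting was made before any count result was seen. Clonality was measured at the same number of cells per mouse over 100 random draws and compared with an exact permutation test, for which 0.333 is the smallest p. Shares of single mice have exact Clopper-Pearson intervals.

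Genes were named by a rule. Tlr7 came first, then up to 10 higher and 10 lower genes with the largest log2 change among those past the threshold, with a mean of at least 20 vpm in the higher group and both SLE.yaa mice on the same side of both WT mice. Immunoglobulin and T cell receptor segments were left out of this ranking, except Jchain. Then came up to 4 called genes of each list by smallest p, up to 10 receptor genes past the threshold, and the largest clone of each mouse. The tests named in the plan, the lists, the naming rule and 75 alternatives were fixed before the data were examined, and 35 alternatives were added later. Every called gene named by the rule had both SLE.yaa mice on the same side of both WT mice.

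The procedure was tested on simulated data, with a dispersion between mice fixed at 0.01 for genes and 0.05 for counts. The rates below hold for that spread alone, and genes that vary more between mice are recovered less often. Of 100 genes changed 2-fold, 100 were recovered over all cells, 100 in B cells, 97 in CD4 T cells, 92 in CD8 T cells and 89 in myeloid cells, but 82 in Mac, 47 in neutrophils, 41 in early B cells, 34 in DC, 25 in B-ISG and 15 in NK cells. False calls made up 2.54% to 6.44% in the 5 main comparisons. Lists moved in the simulation were recovered 20 of 20 times, with 0 to 3 false calls among 20 unmoved lists. These lists were drawn at random, so they cannot test the preset correlation for genes that move together. A 4-fold change was recovered in 60 of 60 cell types, 59 of 60 isotypes, 47 of 60 IGHV, 51 of 60 TRBV and 29 of 60 TRAV genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16 were used.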

Results

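Spleen cells enriched for CD45, the surface protein of white blood cells, were profiled from 4 male mice. The 2 WT mice were of strain C57BL/6. The 2 SLE.yaa mice were of strain B6.Sle1yaa, which carries the Sle1 lupus susceptibility interval of chromosome 1 and Yaa, a translocation of the distal X chromosome onto the Y chromosome that includes Tlr7. Each mouse gave an expression library, a B cell receptor library and a T cell receptor library. The expression table held 22285 cells, with 5497 in WT 1, 5697 in WT 2, 4961 in SLE.yaa 1 and 6130 in SLE.yaa 2. Median UMI counts per cell were 3467, 3670, 4695 and 4050 in the same order, and the total UMI counts were 21793635, 23700502, 26273157 and 28877299. Heavy chains were read in 3500, 3773, 3594 and 2873 cells, and a usable pair of an alpha and a beta chain in 907, 987, 939 and 634 cells. The mouse was the replicate throughout, so every ± is the SD over n = 2 mice. Expression is given as the mean depth-adjusted value after scaling to a sum of 1000000 per mouse (vpm), and p-values are two-sided. Positions of genes are those of GRCm38. The comparisons address which lymphocytes formed clones in lupus-prone mice and which myeloid cells expanded.

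The cells of SLE.yaa spleens held larger shares of plasma cells, of cells annotated DC (dendritic cells) and of cells annotated Mac. Shares of NK cells and early B cells were smaller. Nearly all cells annotated Mac held monocyte markers and few held macrophage markers, as given below. The types are those the authors annotated. Plasma cells made up 0.218% (0.113 to 0.381) and 0.193% (0.0964 to 0.345) of the cells of WT 1 and WT 2, against 6.85% (6.17 to 7.59) and 4.68% (4.17 to 5.24) in SLE.yaa 1 and SLE.yaa 2, with exact Clopper-Pearson 95% intervals in parentheses. These intervals, here and throughout, cover counting error only. The log2 change in the plasma cell share was 4.79 (edgeR, adjusted p = 3.57e-09). Cells annotated DC rose from 1.40% and 1.30% to 5.24% (4.64 to 5.9) and 4.73% (4.21 to 5.29), a log2 change of 1.88 (adjusted p = 0.000144). Cells annotated Mac rose from 6.82% (6.17 to 7.52) and 2.97% (2.54 to 3.44) to 11.1% (10.2 to 12) and 24.2% (23.2 to 25.3), a log2 change of 1.85 (adjusted p = 0.00102). NK cells fell from 2.16% and 2.05% to 1.01% and 0.750%, and early B cells from 4.77% and 4.28% to 2.02% and 2.77% (log2 changes of −1.27 and −0.91, adjusted p = 0.00661 and 0.0360). The other 7 types did not pass the test. Among them, neutrophils had a mean share of 3.04% in WT and 5.50% in SLE.yaa (adjusted p = 0.0522), CD8 T cells 9.07% and 5.69% (adjusted p = 0.0966), CD4 T cells 14.6% and 10.9% (adjusted p = 0.298) and B cells 58.3% and 44.9% (adjusted p = 0.312).

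The plasma cell call held with each mouse left out, and the other 4 calls did not all hold. With a mouse left out, the log2 change was 1.81 to 1.96 for DC, −1.49 to −1.06 for NK cells, −1.17 to −0.71 for early B cells and 1.18 to 2.57 for Mac. The Mac change had an adjusted p of 0.102 without WT 2, 0.0806 without SLE.yaa 1 and 0.312 without SLE.yaa 2, the DC change one of 0.0558 without WT 2, and the NK change 0.132 without WT 1 and 0.102 without WT 2. The early B cell change had 0.209 without WT 1, 0.196 without WT 2 and 0.0806 without SLE.yaa 1. With TMM factors over types, Mac had a log2 change of 2.21 (adjusted p = 0.105) and early B cells one of −0.59 (adjusted p = 0.239), and among the 8 types other than plasma cells, DC, Mac and neutrophils 0 passed (edgeR, 1 at an unadjusted p under 0.05), with NK cells at 0.0506. Of the cells annotated Mac, 99.7%, 97.6%, 99.3% and 98.7% in WT 1, WT 2, SLE.yaa 1 and SLE.yaa 2 held 3 or more of 11 monocyte markers, and 1.33%, 2.37%, 2.91% and 1.95% held 3 or more of 10 macrophage markers. Of the cells annotated DC, 5.19% and 12.2% in WT and 79.6% and 73.8% in SLE.yaa held 3 or more macrophage markers. Without those cells the log2 change in the DC share was −0.0945 (edgeR, adjusted p = 0.824), with a filter that follows the change itself.

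**Figure D1:**
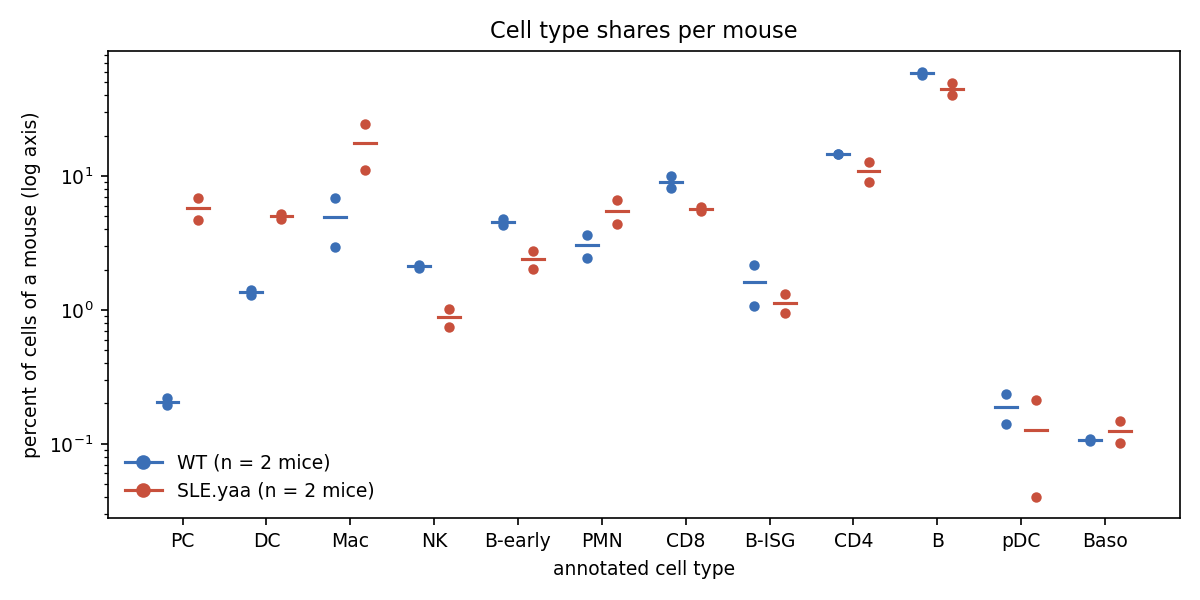
Share of each annotated cell type in percent of the cells of a mouse, on a logarithmic axis. Each mouse has 1 point, bars mark the group means, and WT and SLE.yaa are in different colours. Plasma cells lie at 0.218% and 0.193% in WT and at 6.85% and 4.68% in SLE.yaa.

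Across all cells together, 672 of 8544 genes passed the test, 514 higher and 158 lower in SLE.yaa (limma), a comparison that mixes cell composition with expression. Without scaling between mice 1467 were higher and 72 lower. Tlr7, the endosomal receptor for single-stranded RNA that lies in the Yaa segment, rose from 20.3 ± 2.11 to 65.8 ± 18.5 vpm, a log2 change of 1.30 (adjusted p = 0.0107). With immunoglobulin segments left out of the ranking, the highest changes were in C1qb and Jchain. C1qb, a chain of complement C1q, rose from 2.83 ± 0.168 to 206 ± 21.7 (log2 change 4.07, limma adjusted p = 2.54e-05). Jchain, which joins IgM and IgA multimers, rose from 252 ± 4.25 to 4670.2 ± 2462 (log2 change 4.05, limma adjusted p = 0.00246). C1qc, C1qa, the protease inhibitor Slpi, the fatty acid carrier Fabp4, the T cell inhibitory receptor Lag3, Creld2, the Fc receptor Fcgr4 and Apoc2 rose by 2.43 to 3.76 on the log2 scale. Igfbp4 (from 123 ± 3.1 to 20.9 ± 16.6, log2 change -2.21) and the transcription factor Lef1 (from 157 ± 12 to 33.9 ± 16.3, -1.98), both markers of naive T cells, fell most, followed by the NK and T cell granzyme Gzma (from 243 ± 57.8 to 57 ± 0.486, -1.90), Ly6c1 and Dapl1. The complement receptor Cr2, in the Sle1 interval, fell from 279 ± 7.36 to 92.8 ± 11.3 (-1.496), and Nsg2, Txk and Gm2682 by −1.55 to −1.19. Tlr7 lies on chromosome X (167303380 to 167330574) and C1qb on chromosome 4 (136880126 to 136886200). Jchain lies on chromosome 5 (88519809 to 88527897).

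Over the 5 comparisons from all cells to myeloid cells, camera with its preset correlation called 53 list shifts, of which 0 held with an estimated correlation, and fry called 32. The fry calls were, across all cells, the Yaa, germinal centre, age-associated, plasma cell, follicular helper, cytotoxic, exhaustion, regulatory, immediate early and proliferation lists, the last without a camera call. In B cells they were the Yaa, age-associated, marginal zone and cytotoxic lists, in CD8 T cells the Yaa, plasma cell, follicular helper and exhaustion lists, and in myeloid cells the germinal centre, MHC class II and erythroid lists. In CD4 T cells fry called each list that camera called except MHC class II.

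By fixed list across all cells, 9 of 11 measured plasma cell genes rose, and 11 adjusted over the list alone, among them Creld2 (2.49), Eaf2 (1.95) and Edem1 (1.80). Plasma cell genes had a median log2 change of 1.80 (camera adjusted p = 5.28e-12, or adjusted p = 0.296 with an estimated correlation). Of 27 interferon-stimulated genes 8 rose, and 13 adjusted over the list alone, such as Iigp1 (1.55) and Ifi27l2a (1.09). Interferon-stimulated genes had a median log2 change of 0.45 (camera adjusted p = 1.49e-05, or adjusted p = 0.296 with an estimated correlation). Genes of monocytes rose at 6 of 16, and 12 adjusted over the list alone, with Csf1r at 1.97, Treml4 at 1.59 and Nr4a1 at 1.35. Monocyte genes had a median log2 change of 0.93 (camera adjusted p = 7.27e-07, or adjusted p = 0.398 with an estimated correlation). None of 14 neutrophil genes passed over all genes, and 13 rose adjusted over the list alone. Neutrophil genes had a median log2 change of 1.27 (camera adjusted p = 5.63e-06, or adjusted p = 0.438 with an estimated correlation). Lists of age-associated B cells (7 of 11 higher, 11 adjusted over the list alone), germinal centre B cells (4 of 6, 5), T cell exhaustion (6 of 8, 7), follicular helper T cells (6 of 9, 7) and regulatory T cells (4 of 6, 6) rose, with camera adjusted p of 2.87e-06 or less and adjusted p = 0.264 for each with an estimated correlation. Naive T cell genes fell at 5 of 10, and 8 adjusted over the list alone. Naive genes had a median log2 change of -0.96 (camera adjusted p = 6.06e-06, or adjusted p = 0.315 with an estimated correlation). Activated and cytotoxic T cell genes went both ways, 4 up and 2 down of 14, or 8 and 2 adjusted over the list alone. Cytotoxic genes had a median log2 change of 0.72 (camera adjusted p = 0.00472, or adjusted p = 0.264 with an estimated correlation). Immediate early genes, which cell dissociation can induce, rose at 2 of 10, or 3 adjusted over the list alone, with Jun at 1.22. Immediate early genes had a median log2 change of 0.31 (camera adjusted p = 0.00327, or adjusted p = 0.315 with an estimated correlation). MHC class II genes had 0 of 10 members past the test by limma and 0 adjusted over the list alone, with a list shift downward. MHC class II genes had a median log2 change of -0.22 (camera adjusted p = 0.0331, or adjusted p = 0.505 with an estimated correlation). The marginal zone list (2 up, 4 down of 12, camera adjusted p = 0.0861), the Sle1 interval list (3 up, 1 down of 14, 0.538), and the lists of proliferation (0.389), erythroid cells (0.0749), mitochondrial transcripts (0.0861) and Y-linked genes with Xist (0.389) did not pass. Without SLE.yaa 1, 1776 genes passed instead of 672, and Irf7, Phf11b and Slamf6 lost their calls without a WT mouse. Of the named genes, Mzb1, Edem1, Irf7, Asb2 and Nr4a1 also lost their calls when plasma cells, Mac, DC and neutrophils were left out.

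B cells, taken as the 3 annotated B cell types without plasma cells, had 279 of 7932 genes past the test, 208 higher and 71 lower in SLE.yaa (limma), or 1050 and 34 without scaling between mice. Tlr7 rose from 19.6 ± 0.633 to 54.6 ± 8.69 vpm (log2 change 1.12, adjusted p = 0.000454). Genes of age-associated B cells, an activated subset that carries the transcription factor T-bet and the integrin CD11c, rose at 7 of 9, and 8 adjusted over the list alone. Age-associated B cell genes had a median log2 change of 1.14 (camera adjusted p = 1.65e-18, or adjusted p = 0.174 with an estimated correlation). Among them were Tbx21, which encodes T-bet (from 3.73 ± 2.36 to 33.6 ± 7.16, log2 change 1.67), Itgax, which encodes CD11c (from 0.266 ± 0.0245 to 12.1 ± 0.381, 1.104), Zeb2 (from 58.9 ± 4.39 to 159.8 ± 25.5, 1.29) and the chemokine receptor Cxcr3 (from 1.45 ± 1.24 to 48.5 ± 0.87, 2.36, adjusted p = 3.19e-06). Marginal zone B cell genes fell at 4 of 11, and 5 adjusted over the list alone. Marginal zone genes had a median log2 change of -0.28 (camera adjusted p = 7.69e-06, or adjusted p = 0.174 with an estimated correlation). These were Cr2 (from 433 ± 10.0 to 185 ± 0.552, -1.18, adjusted p = 0.000215), Myof (from 25.8 ± 0.761 to 6.84 ± 0.252, -1.09), the sphingosine phosphate receptor S1pr3 (from 22.3 ± 1.69 to 7.47 ± 2.03, -0.89) and Cd1d1 (from 56 ± 3.15 to 30.6 ± 2.05, -0.70). Cd24a (-1.08), Marcks (-1.02), Nedd4 (-0.82), I730030J21Rik, Niban3, Cecr2 and Dennd2d (-0.76) fell as well. Tbx21 lies on chromosome 11 (97098007 to 97115331) and Cxcr3 on chromosome X (101731535 to 101734147). Cr2 lies on chromosome 1 (195136811 to 195176880).

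Interferon-stimulated genes rose in B cells at 7 of 24, and 11 adjusted over the list alone. Interferon-stimulated genes had a median log2 change of 0.31 (camera adjusted p = 4.08e-09, or adjusted p = 0.326 with an estimated correlation). In B-ISG cells alone the list went down, with 1 of 28 higher and 8 lower, or 2 and 14 adjusted over the list alone (median −0.54, camera adjusted p = 4.15e-12, or 0.437 with an estimated correlation). In early B cells it went up (2 of 22 higher, median 0.74, camera adjusted p = 1.93e-15, or 0.406). Whether the list differed between these types was not tested. In the 3 types together, the members with small p included genes that interferon gamma induces, the GTPases Iigp1 (from 1.06 ± 1.09 to 49.5 ± 12.3, 2.42), Igtp (0.94) and Ifi47 (0.83). Slpi (from 3.09 ± 2.67 to 95.4 ± 24.6, 3.004), the Fc receptor chain Fcer1g (from 4.22 ± 1.66 to 62.9 ± 25.9, 2.31), the cytokine signalling inhibitor Socs3 (from 7.61 ± 0.629 to 65.5 ± 8.72, 2.10), Serpina3g, Serpina3f and Wfdc17 were among the 10 highest. Jchain rose from 5.51 ± 0.666 to 1405 ± 906 (6.35, adjusted p = 7.6e-06), although it rose in T cells and myeloid cells too. Plasma cell genes rose at 6 of 9 and fell at 1, with the same counts adjusted over the list alone. Plasma cell genes had a median log2 change of 0.54 (camera adjusted p = 8.47e-08, or adjusted p = 0.258 with an estimated correlation). Germinal centre genes rose at 2 of 4, 2 adjusted over the list alone, namely the death receptor Fas (from 5.9 ± 0.481 to 24.1 ± 6.2, 1.09) and Eaf2. Germinal centre genes had a median log2 change of 0.26 (camera adjusted p = 0.0175, or adjusted p = 0.301 with an estimated correlation). The Sle1 interval list did not shift as a whole (camera adjusted p = 0.165), with Fcer1g, Slamf6 (1.05) and Slamf1 (0.99) higher and Cr2 lower.

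Markers of other cells also moved in the B cell comparison. All 3 measured genes of the activated T cell list rose, over all genes and adjusted over the list alone, of which Cxcr3 and Tbx21 are on the age-associated B cell list too. Cytotoxic genes had a median log2 change of 1.67 (camera adjusted p = 1.78e-09, or adjusted p = 0.174 with an estimated correlation). The monocyte genes Ly6c2 (1.61) and Lyz2 (1.65) rose, 2 of 5 and 3 adjusted over the list alone. Monocyte genes had a median log2 change of 0.50 (camera adjusted p = 0.0014, or adjusted p = 0.258 with an estimated correlation). The haemoglobin gene Hba-a2 was listed at 0 in WT and at 52.2 ± 22.3 in SLE.yaa, while the erythroid list rose at 1 and fell at 1 of 5, or 3 and 1 adjusted over the list alone. Erythroid genes had a median log2 change of 1.74 (camera adjusted p = 0.0127, or adjusted p = 0.483 with an estimated correlation). The follicular helper T cell list had a median of -0.08, a mean of 0.28 and an upward test (camera adjusted p = 0.236). The lists of naive T cells (0.236), neutrophils (0.681), MHC class II (0.127), proliferation (0.957), immediate early genes (0.281), mitochondrial transcripts (0.681) and Y-linked genes (0.777) did not pass by camera adjusted p. The count of 279 genes became 138 without WT 1, 172 without WT 2, 727 without SLE.yaa 1 and 446 without SLE.yaa 2. Eaf2, Edem1, Niban3 and Cecr2 were among the genes that lost their calls without a WT mouse, and of 45 genes named by the rule 40 kept theirs with each mouse left out.

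The receptor libraries showed class switching in SLE.yaa mice, with IGHG2C the largest change. Shares are of the heavy-chain cells with an isotype. IGHG2C, the constant gene of IgG2c, was read in 0.0572% (0.00693 to 0.206) and 0.0531% (0.00643 to 0.192) of those of WT 1 and WT 2. In SLE.yaa 1 and SLE.yaa 2 it was read in 12.2% (11.2 to 13.3) and 10.5% (9.37 to 11.7). This was 2 cells in each WT mouse against 433 and 298 cells, a log2 change of 7.60 (edgeR, adjusted p = 2.31e-06). IGHG2B rose from a mean of 0.170% to 6.71% (log2 change 5.31, adjusted p = 3.86e-05), IGHG3 from 0.0551% to 1.96% (5.06, 5.94e-05), IGHG1 from 0.128% to 1.55% (3.62, 0.00182) and IGHA from 0.153% to 1.03% (2.75, 0.00151). IGHM fell from 84.3% to 52.1% (−0.69, adjusted p = 0.0401), and IGHD rose from 15.2% to 25.2% (0.73, 0.0403). IGHE was read in 2 cells, both of SLE.yaa 1 (adjusted p = 0.193), and in 0 cells of the WT mice, which has exact upper limits of 0.105% and 0.0978%. Leaving out WT 1 raised the adjusted p of IGHM and IGHD to 0.133 and leaving out WT 2 to 0.158, and without SLE.yaa 1 IGHG1 had 0.0734. Among annotated plasma cells, 235 of 331 (71.0%) and 230 of 279 (82.4%) were switched in SLE.yaa 1 and SLE.yaa 2, against 1 of 11 in each WT mouse. Among cells annotated B, 2.53% and 4.39% were switched in SLE.yaa 1 and SLE.yaa 2, against 0.511% and 0.201% in WT 1 and WT 2. The shares over all heavy-chain cells also include barcodes outside the expression table. Ighg2c in the expression libraries changed the same way across all cells, from 0.166 to 4348 vpm (log2 change 8.73).

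**Figure D2:**
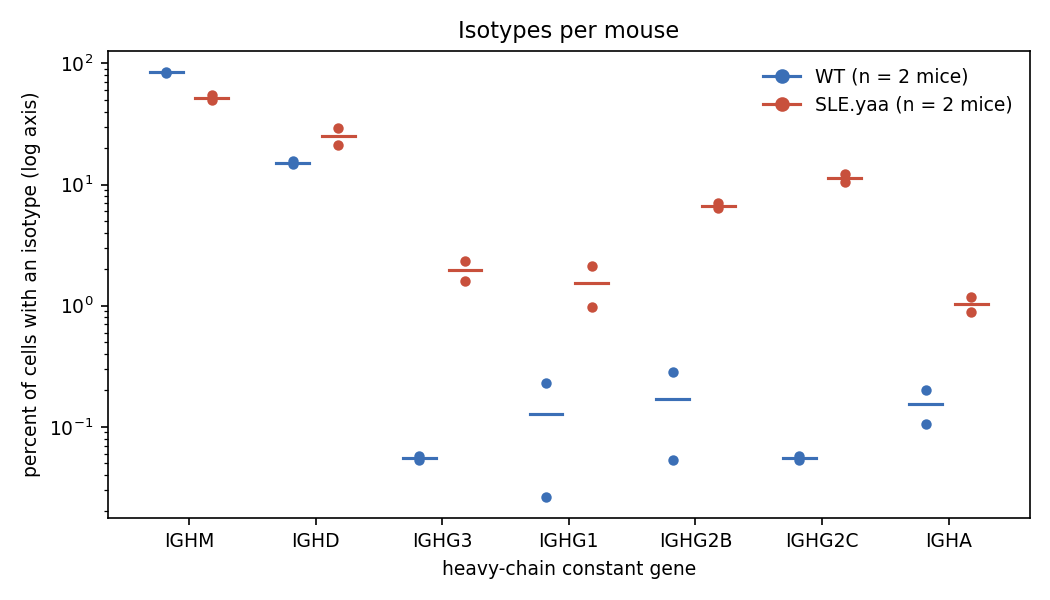
Share of the heavy-chain isotypes other than IGHE in percent of the cells with an isotype, on a logarithmic axis. Each mouse has 1 point, bars mark the group means, and WT and SLE.yaa are in different colours. IGHG2C lies at 0.0572% and 0.0531% in WT and at 12.2% and 10.5% in SLE.yaa.

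More heavy-chain cells of SLE.yaa mice belonged to clones, defined by the same V gene, J gene and heavy CDR3 nucleotides within a mouse. At 2873 cells drawn per mouse, 3.03% and 1.76% of cells lay in clones of 2 or more cells in WT 1 and WT 2, and 11.5% and 8.70% in SLE.yaa 1 and SLE.yaa 2. The means were 2.395 ± 0.892% and 10.1 ± 1.95% (SD, n = 2), a difference of 7.69 percentage points (exact permutation p = 0.333, the smallest that 2 against 2 mice can give). Inverse Simpson diversity was 2781 ± 57.4 and 2177 ± 243. Of the SLE.yaa cells in such clones, 30.7% and 42.8% were annotated as plasma cells and 56.2% and 38.4% lay outside the expression table. The difference was 3.81 percentage points over barcodes in the expression table, and 0.00311 over those annotated B, B-ISG and B-early. The largest clone of SLE.yaa 1 used IGHV1-82 and IGHJ3 in 30 cells, and that of SLE.yaa 2 used IGHV1-53 and IGHJ3 in 12 cells, both IGHG2C. Of the 30 cells, 27 lay outside the expression table, 2 were annotated as plasma cells and 1 as Mac. Of the 12 cells, 5 lay outside it and 7 were annotated as plasma cells. The largest clones of WT 1 and WT 2 both used IGHV11-2 and IGHJ1, with 8 and 3 cells, all IGHM. Of 169 and 94 clones with 2 or more cells in SLE.yaa 1 and SLE.yaa 2, 93 and 59 held switched cells alone, against 1 of 56 and 0 of 43 in WT 1 and WT 2.

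V gene usage differed little when each clone counted once. Of 70 IGHV genes tested, 2 passed (edgeR), IGHV8-8 from 2.43% to 4.05% of clones (log2 change 0.74, adjusted p = 0.00035) and IGHV1-54 from 1.05% to 0.426% (−1.27, adjusted p = 0.0426). Neither passed with a mouse left out, although the log2 changes stayed at 0.69 to 0.78 and −1.50 to −1.11, and IGHV8-8 had an adjusted p of 0.183 without WT 1, 0.204 without WT 2, 0.267 without SLE.yaa 1 and 0.285 without SLE.yaa 2, and IGHV1-54 had 0.25, 0.204, 0.267 and 0.321. At the same number of clones, 1.72 heavy CDR3 amino acid sequences were shared between the WT mice, 5.06 between the SLE.yaa mice and 0.65 to 3.15 between mice of different groups, as means over 100 draws and with no test.

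CD4 T cells had 2369 of 8415 genes past the test, with 1338 higher and 1031 lower (limma), or 2056 and 485 without scaling between mice. All 11 measured genes of follicular helper T cells, the T cells that help B cells in germinal centres, rose, also adjusted over the list alone. Follicular helper genes had a median log2 change of 2.37 (camera adjusted p = 1.59e-14, or adjusted p = 0.156 with an estimated correlation). Sostdc1 was listed at 0 in WT and at 378 ± 45.4 vpm in SLE.yaa, and Il21, the cytokine of these cells, at 0 and 97.6 ± 19.8. The inhibitory receptor Pdcd1 rose from 13.4 ± 1.61 to 289.8 ± 49 (log2 change 3.67, adjusted p = 1.42e-10), and the transcription factors Maf from 36.2 ± 7.06 to 449 ± 91.6 (3.31) and Bcl6 (0.97) rose as well. All 7 measured exhaustion genes rose, also adjusted over the list alone, with Lag3 from 4.14 ± 0.0645 to 499.9 ± 4.69 (5.17, adjusted p = 1.11e-12), Tigit from 18.8 ± 1.12 to 485 ± 9.14 (4.11) and Ctla4 from 29.3 ± 1.87 to 181 ± 6.58 (2.28). Exhaustion genes had a median log2 change of 2.28 (camera adjusted p = 3.26e-12, or adjusted p = 0.156 with an estimated correlation). All 8 regulatory T cell genes rose, also adjusted over the list alone, with Tnfrsf4 (from 65.1 ± 3.28 to 578 ± 13.3, 2.97) and Ikzf2 (from 76.3 ± 3.63 to 552 ± 152, 2.68). Regulatory T cell genes had a median log2 change of 1.85 (camera adjusted p = 5.11e-10, or adjusted p = 0.184 with an estimated correlation). Of 14 activated and cytotoxic genes 12 rose and 1 fell, or 12 and 2 adjusted over the list alone, with Ifng (from 0.839 ± 0.295 to 47.2 ± 4.23, 2.397), Tnfrsf9 (from 19.1 ± 0.672 to 204 ± 2.95, 2.88) and Gzmk (2.45). Cytotoxic genes had a median log2 change of 2.23 (camera adjusted p = 1.66e-09, or adjusted p = 0.184 with an estimated correlation). Sostdc1 lies on chromosome 12 (36314169 to 36318452) and Il21 on chromosome 3 (37222759 to 37232636). Pdcd1 lies on chromosome 1 (94038305 to 94052553) and Lag3 on chromosome 6 (124904359 to 124912434). Tigit lies on chromosome 16 (43626137 to 43665125).

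Naive T cell genes fell in CD4 T cells at 9 of 10, with the same count adjusted over the list alone. Naive genes had a median log2 change of -1.76 (camera adjusted p = 2.64e-09, or adjusted p = 0.24 with an estimated correlation). Igfbp4 fell from 664 ± 7.89 to 90.9 ± 70.1 (log2 change -2.94), the chromatin organiser Satb1 from 419 ± 23 to 59.5 ± 20.1 (-2.66), Lef1 from 635 ± 5.74 to 140.2 ± 35.9 (-2.12) and the lymph node homing receptor Ccr7 from 368 ± 14.4 to 98 ± 40.4 (-1.86). The lowest was Ly6c1 (from 233 ± 6.03 to 18.2 ± 10.2, -3.16), and Actn1, Pdlim4, Dapl1, St8sia6, Pde3b and Atp1b1 fell by −2.53 to −2.02. Eea1, an early endosome tether (from 24.2 ± 3.17 to 566 ± 76.8, 4.07), S100a6 (3.99), the transcription factor Bhlhe40 (from 8.18 ± 6.21 to 238 ± 20.4, 3.81), S100a4 (3.48) and Gpm6b (from 6.61 ± 0.461 to 184 ± 14.2, 3.54) rose, and Spp1, which encodes osteopontin, was listed at 0 and 129.6 ± 9.06. Tlr7 was low, from 5.61 ± 0.532 to 11.9 ± 0.595 (0.49, adjusted p = 0.0194), and its call was lost without WT 1 (0.46, adjusted p = 0.21) and without WT 2 (0.52, 0.14). Igfbp4 lies on chromosome 11 (99040005 to 99052655) and Satb1 on chromosome 17 (51736187 to 51833290). Lef1 lies on chromosome 3 (131110297 to 131224357) and Ly6c1 on chromosome 15 (75044018 to 75048920).

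Further lists moved in CD4 T cells. Age-associated B cell genes rose at 7 of 8, the same adjusted over the list alone, with Cxcr3 (2.72), Ahnak (2.64) and Nt5e (2.36). Age-associated B cell genes had a median log2 change of 2.10 (camera adjusted p = 6.55e-09, or adjusted p = 0.184 with an estimated correlation). Plasma cell genes rose at 5 of 8, the same adjusted over the list alone, with Irf4 (1.84) and Prdm1 (1.94), transcription factors of activated T cells too, and Jchain (from 2.01 ± 0.613 to 76.6 ± 69.7, 2.57). Plasma cell genes had a median log2 change of 0.79 (camera adjusted p = 0.00119, or adjusted p = 0.204 with an estimated correlation). Germinal centre genes rose at 3 of 4, the same adjusted over the list alone, with S1pr2 (1.21), and monocyte genes at 6 of 8, the same adjusted over the list alone, with Cxcl10 (2.58) and Cybb (2.25). Germinal centre genes had a median log2 change of 0.82 (camera adjusted p = 0.00806, or adjusted p = 0.204 with an estimated correlation). Monocyte genes had a median log2 change of 0.97 (camera adjusted p = 6.93e-05, or adjusted p = 0.184 with an estimated correlation). Immediate early genes rose at 5 of 9, the same adjusted over the list alone, with Junb (1.41) and Dusp1 (1.57). Immediate early genes had a median log2 change of 0.70 (camera adjusted p = 0.0087, or adjusted p = 0.327 with an estimated correlation). MHC class II genes fell at 3 of 9, or 7 adjusted over the list alone. MHC class II genes had a median log2 change of -0.42 (camera adjusted p = 0.00911, or adjusted p = 0.397 with an estimated correlation). The interferon list had 9 genes higher and 2 lower of 26, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.0508), nor did the Sle1 list (0.235), proliferation (0.118, with Mki67 at 1.15), mitochondrial transcripts (0.417) and Y-linked genes (0.764). The marginal zone list did not pass (0.602), and camera put it down where fry put it up. The count of 2369 genes was 1542 without WT 1, 1398 without WT 2 and 1500 without SLE.yaa 2, and 66 of the 73 genes named by the rule kept their calls with each mouse left out.

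**Figure D3:**
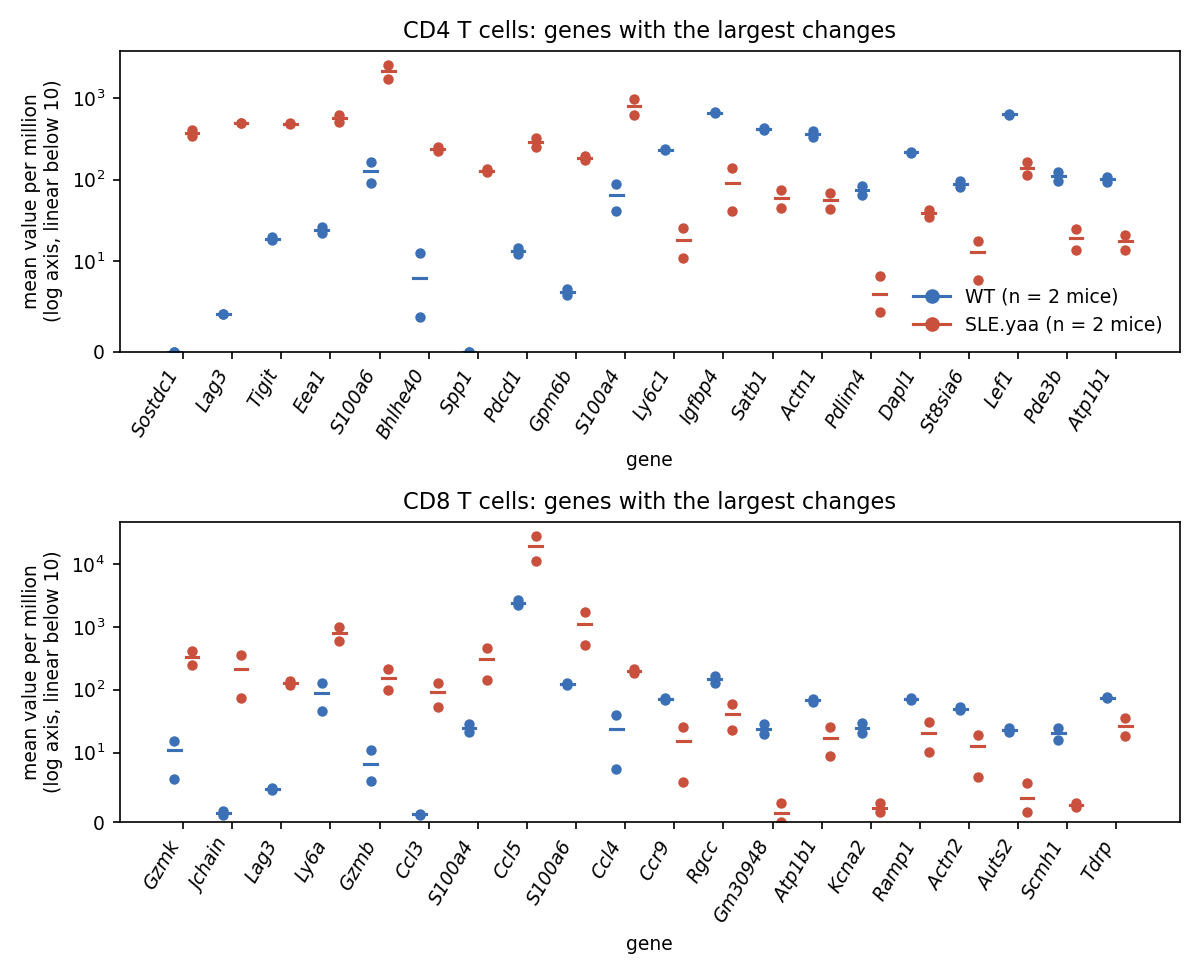
Mean value in vpm for genes named in CD4 and CD8 T cells, with 1 point per mouse and WT and SLE.yaa in different colours. The axis is logarithmic except at low values, where it is linear. Lag3 in CD4 T cells lies near 4.14 vpm in WT and near 499.9 in SLE.yaa.

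CD8 T cells of SLE.yaa mice carried more cytotoxic and inhibitory receptor transcripts, with 261 of 8281 genes past the test, 207 higher and 54 lower (limma). Of 15 activated and cytotoxic genes 12 rose, and 14 adjusted over the list alone. Cytotoxic genes had a median log2 change of 1.53 (camera adjusted p = 1.78e-22, or adjusted p = 0.223 with an estimated correlation). The granzymes Gzmk (from 10.8 ± 6.44 to 331 ± 119, log2 change 4.02, adjusted p = 2.15e-05) and Gzmb (from 8.43 ± 3.62 to 156 ± 78.6, 3.10), the chemokine Ccl5 (from 2422 ± 304 to 19543 ± 12035, 2.86) and the transcription factor Eomes (from 55.4 ± 4.55 to 197 ± 32.3, 1.65) were among them. Exhaustion genes rose at 6 of 8, with 7 up and 1 down adjusted over the list alone, including Lag3 (from 4.78 ± 0.239 to 129 ± 13.7, 3.23), Tigit (from 7.2 ± 0.701 to 108 ± 35.8, 2.74), Pdcd1 (from 4.36 ± 0.832 to 54.9 ± 3.49, 2.18) and Entpd1 (1.38). Exhaustion genes had a median log2 change of 1.28 (camera adjusted p = 1.24e-11, or adjusted p = 0.223 with an estimated correlation). Ly6a, S100a4, S100a6 and the chemokines Ccl3 and Ccl4 rose by 2.83 to 3.15. Interferon-stimulated genes rose at 6 of 23, and 16 adjusted over the list alone, with Ifi27l2a at 1.62. Interferon-stimulated genes had a median log2 change of 0.63 (camera adjusted p = 1.26e-12, or adjusted p = 0.223 with an estimated correlation). Monocyte genes rose at 4 of 5, and 5 adjusted over the list alone, among them the migration receptors Ccr2 (2.02) and Cx3cr1 (2.25). Monocyte genes had a median log2 change of 2.02 (camera adjusted p = 8.25e-09, or adjusted p = 0.223 with an estimated correlation). Jchain rose here too (from 1.39 ± 0.408 to 217 ± 200.2, 3.96). Gzmk lies on chromosome 13 (113171630 to 113180965) and Ccl5 on chromosome 11 (83525778 to 83530518).

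The gut homing receptor Ccr9 (from 70.5 ± 3.35 to 15.5 ± 13.7, log2 change -1.77, adjusted p = 0.0109) fell most in CD8 T cells, followed by Rgcc (-1.70), Gm30948, Atp1b1, Kcna2, Ramp1 (from 71.2 ± 3.5 to 20.5 ± 14.6, -1.499), Actn2, Auts2, Scmh1 and Tdrp (-1.25). Naive genes fell at 2 of 10, or 4 adjusted over the list alone, namely Satb1 (-0.89) and Lef1 (-1.14). Naive genes had a median log2 change of -0.56 (camera adjusted p = 0.000281, or adjusted p = 0.376 with an estimated correlation). Follicular helper genes rose at 4 of 8 and 7 adjusted over the list alone, and Sle1 interval genes at 2 of 10, or 4, with Slamf7 at 1.52. Follicular helper genes had a median log2 change of 0.68 (camera adjusted p = 2.9e-09, or adjusted p = 0.214 with an estimated correlation). Sle1 interval genes had a median log2 change of 0.44 (camera adjusted p = 0.000169, or adjusted p = 0.223 with an estimated correlation). The lists of age-associated B cells (6 of 7, 6 adjusted over the list alone), plasma cells (3 of 8, 6) and regulatory T cells (2 of 4, 3) rose as well. Age-associated B cell genes had a median log2 change of 1.27 (camera adjusted p = 2.77e-08, or adjusted p = 0.223 with an estimated correlation). Plasma cell genes had a median log2 change of 0.69 (camera adjusted p = 7.17e-07, or adjusted p = 0.214 with an estimated correlation). Regulatory T cell genes had a median log2 change of 0.71 (camera adjusted p = 0.00028, or adjusted p = 0.267 with an estimated correlation). The lists of germinal centre B cells (0.336), marginal zone B cells (0.153), neutrophils (0.336), MHC class II (0.291), proliferation (0.188), immediate early genes (0.179), mitochondrial transcripts (0.383) and Y-linked genes (0.786) did not pass by camera adjusted p. Tlr7 had 4.21 ± 1.81 in WT and 11.4 ± 0.686 in SLE.yaa and did not pass (log2 change 0.60, adjusted p = 0.161). These counts rested on single mice, with 76 genes without WT 1, 47 without WT 2, 1752 without SLE.yaa 1 and 554 without SLE.yaa 2. Without one or the other WT mouse, Ccr9, Rgcc, Atp1b1, Ramp1, Actn2, Tdrp, Satb1, Lef1, Slamf6, Tbx21, Mzb1, Ikzf2 and Ctla4 lost their calls, and 23 of 49 genes named by the rule kept theirs with each mouse left out. Ccr9 lies on chromosome 9 (123767211 to 123783457).

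The changes in CD4 and CD8 T cells differed for 529 of 7932 genes when the difference itself was tested (limma, within mice). Of 25 named genes, 16 differed. The fall of Igfbp4 was larger in CD4 T cells (difference −2.25, adjusted p = 0.000151), as were those of Satb1 (−1.76) and Lef1 (−0.99), and so were the rises of Lag3 (1.94), Pdcd1 (1.498), Tigit (1.36) and Bhlhe40 (1.75). On log2 of vpm plus 10, the rises of Gzmk (−1.58, limma adjusted p = 0.0163), Gzmb (−1.43) and Ccl3 (−1.62) were larger in CD8 T cells. The pseudocount of 10 lowers rises from values near 0. In WT 1, CD4 T cells outside clones averaged 0 for Gzmk and Gzmb. The order of the fold changes without the pseudocount was not tested. For Ccl5 (−0.19, adjusted p = 0.892) and S100a6 (1.15, 0.0883) no difference passed.

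T cell clones, defined by the same beta V gene, J gene and CDR3 nucleotides within a mouse, took up more cells in SLE.yaa mice. At 634 cells drawn per mouse, 2.96% and 0.514% of cells lay in clones of 2 or more cells in WT 1 and WT 2, and 22.6% and 28.9% in SLE.yaa 1 and SLE.yaa 2. The means were 1.74 ± 1.73% and 25.7 ± 4.41% (SD, n = 2), a difference of 24.0 percentage points (exact permutation p = 0.333). Among CD4 T cells the means were 2.42 ± 2.35% and 24.7 ± 0.603%, and among CD8 T cells 0% and 13.9 ± 6.17%. At 142 CD8 cells drawn per mouse, a count of 0 has an exact upper limit of 2.56%. The largest clone of SLE.yaa 1 held 19 cells with TRBV12-2/13-2 and TRBJ2-5, 11 of them annotated CD4, and that of SLE.yaa 2 held 10 cells with TRBV26 and TRBJ1-5, 8 of them annotated CD8. The largest clone of WT 1 held 15 cells with TRBV3 and TRBJ2-4, 13 of them annotated CD4, and in WT 2 no clone exceeded 2 cells. The mean share of the largest clone was 0.960% and 1.81% (exact permutation p = 0.667). None of 20 TRBV and 39 TRAV genes passed in usage by clones (edgeR), with 1 and 3 genes at an unadjusted p under 0.05, and TRAV16N came nearest, at 1.60% and 3.77% (adjusted p = 0.0917). At the same number of clones, 0.59 beta CDR3 amino acid sequences were shared between the WT mice and 3.26 between the SLE.yaa mice, with 0 to 1.82 across groups.

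**Figure D4:**
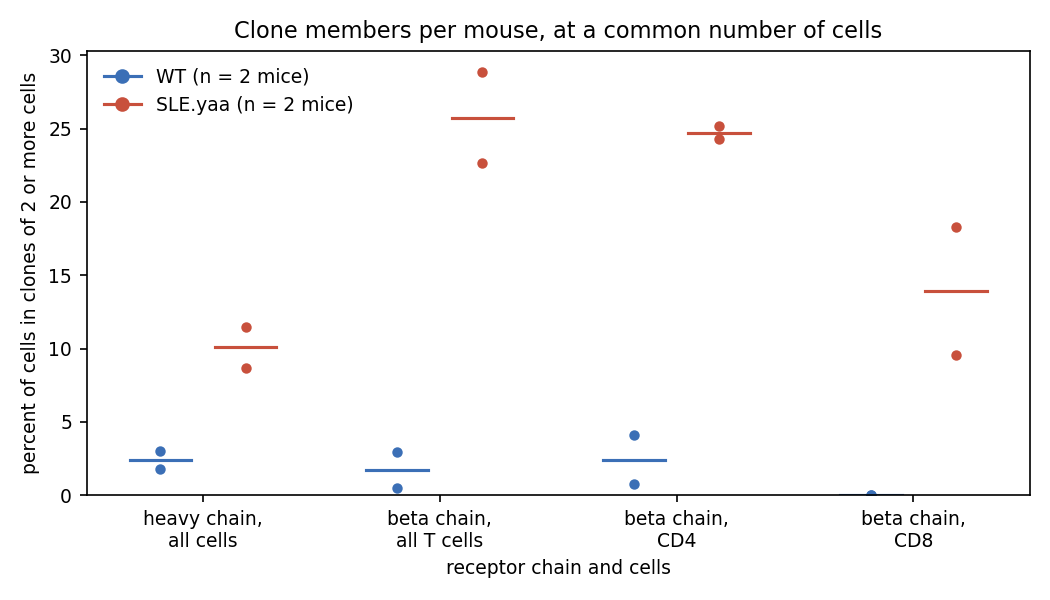
Percent of cells in clones of 2 or more cells, with 1 point per mouse, for heavy chains, all T cells, CD4 T cells and CD8 T cells at the same number of cells drawn per mouse. T cells lie at 2.96% and 0.514% in WT and at 22.6% and 28.9% in SLE.yaa.

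Myeloid cells, taken as the cells annotated Mac and DC, had 364 of 8220 genes past the test, 218 higher and 146 lower (limma). All 10 genes of MHC class II presentation fell, also adjusted over the list alone. MHC class II genes had a median log2 change of -1.35 (camera adjusted p = 2.1e-18, or adjusted p = 0.177 with an estimated correlation). Without the DC, 7 of 10 passed. H2-Aa fell from 3618 ± 101.5 to 1416 ± 9.68 vpm (log2 change -1.35), H2-Ab1 from 1817 ± 73 to 712 ± 23.4 (-1.34), the invariant chain Cd74 from 11879 ± 628 to 4309 ± 412 (-1.46, adjusted p = 0.0017) and their transcriptional activator Ciita from 129 ± 25.6 to 35.2 ± 1.23 (-1.61). Sle1 interval genes fell at 4 of 13, and 7 adjusted over the list alone while 3 rose, among them the inhibitory Fc receptor Fcgr2b (from 179.8 ± 23.5 to 43 ± 15.6, -1.87), Slamf7 (from 126 ± 30.1 to 30.1 ± 6.33, -1.76), Fcgr3 (-1.32) and Ly9 (-0.92). Sle1 interval genes had a median log2 change of -0.38 (camera adjusted p = 0.00592, or adjusted p = 0.505 with an estimated correlation). Of 17 monocyte genes 4 rose and 5 fell, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.646). By type, 6 of 15 rose and 1 fell in DC (median 0.58, camera adjusted p = 0.00343, or 0.412 with an estimated correlation), and 3 of 15 rose and 5 fell in Mac (median 0.14, camera adjusted p = 0.848). Of the Sle1 genes, 5 of 12 rose and 2 fell in DC (median 0.56, camera adjusted p = 0.153), and 4 of 11 fell in Mac (median −0.48, camera adjusted p = 8.48e-05, or 0.393 with an estimated correlation). The classical monocyte genes F13a1 (from 246 ± 10.2 to 70.9 ± 6.28, -1.66), Ccr2 (from 301 ± 55 to 112 ± 4.11, -1.34) and Lyz2 (from 12118 ± 342 to 6223 ± 353, -0.96) fell, and the cytokine Il1b rose from 139 ± 0.979 to 393 ± 73 (1.43, adjusted p = 0.0023). Tlr7 rose from 91 ± 0.479 to 162 ± 16.7 (0.77, adjusted p = 0.0212), a call that was lost without SLE.yaa 2 (0.68, adjusted p = 0.19). H2-Aa lies on chromosome 17 (34282744 to 34287823) and Cd74 on chromosome 18 (60803849 to 60812652). Fcgr2b lies on chromosome 1 (170960558 to 170976071) and Il1b on chromosome 2 (129364569 to 129371164).

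C1qa (from 30.8 ± 21.3 to 759.8 ± 444, log2 change 4.21), C1qb (from 43.3 ± 22 to 1083 ± 539, 4.33) and C1qc (from 38.5 ± 25.9 to 838 ± 449, 4.13) rose in the myeloid comparison through the cells annotated DC. Without DC, C1qb changed by −0.06 (adjusted p = 0.94). The B cell coreceptor Cd72 (from 14.5 ± 6.41 to 239 ± 28.1, 3.36), Fcrl5 (from 1.77 ± 1.73 to 113 ± 43.9, 3.34), the adhesion molecule Pecam1 (from 22.9 ± 8.4 to 197 ± 50.2, 2.65), Jchain (from 2.49 ± 3.52 to 112 ± 107, 2.98) and the macrophage protein Cd5l (2.92) rose as well. All 4 erythroid genes rose, also adjusted over the list alone, with Hbb-bs from 1.495 ± 2.11 to 240.1 ± 13.1 (4.45), while Hba-a1 was listed at 0 and 99.4 ± 10.7 and Hba-a2 at 0 and 93.2 ± 15.3. Erythroid genes had a median log2 change of 3.40 (camera adjusted p = 1.06e-11, or adjusted p = 0.177 with an estimated correlation). The rise of Hbb-bs lay in DC, where it averaged 3.004 and 5.68 depth-adjusted values per cell in SLE.yaa 1 and SLE.yaa 2, against 0 and 0.00404 in Mac. H2-M2 was at 44.8 ± 31.1 in WT and listed at 0 in SLE.yaa, and H2-Eb2, Klrd1, H2-Oa and Cd7 fell by −1.76 to −1.47. Interferon-stimulated genes had 1 higher and 1 lower of 28, or 1 and 3 adjusted over the list alone, with a list shift downward. Interferon-stimulated genes had a median log2 change of -0.17 (camera adjusted p = 0.00336, or adjusted p = 0.505 with an estimated correlation). By type the list had opposite signs, a difference that was not tested and that fry called in neither type (adjusted p = 0.0862 in DC and 0.199 in Mac). In DC, most of which held macrophage markers in SLE.yaa but not in WT, 7 of 29 rose, or 12 up and 1 down adjusted over the list alone (median 0.74, camera adjusted p = 0.000373, or 0.412 with an estimated correlation). In Mac 2 of 25 fell, or 10 adjusted over the list alone (median −0.50, camera adjusted p = 7.46e-08, or 0.393 with an estimated correlation). Mitochondrial transcripts, a sign of RNA quality, rose at 1 of 10, or 10 adjusted over the list alone. Mitochondrial transcripts had a median log2 change of 0.54 (camera adjusted p = 7.36e-07, or adjusted p = 0.505 with an estimated correlation). Germinal centre genes rose at 1 of 3, or 3 adjusted over the list alone. Germinal centre genes had a median log2 change of 0.63 (camera adjusted p = 0.0199, or adjusted p = 0.505 with an estimated correlation). The T cell exhaustion list had a median of -0.13, a mean of 0.03 and a downward test (camera adjusted p = 0.703), and the immediate early list a median of 0.14, a mean of -0.04 and an upward test (0.533). The lists of age-associated B cells (0.402), plasma cells (0.452), marginal zone B cells (0.424), follicular helper (0.196), cytotoxic (0.268) and naive T cells (0.268), neutrophils (0.436), proliferation (0.319) and Y-linked genes (0.354) did not pass. Of the 364 genes 59.9% were higher, but 38.3% of those called with values scaled to the sum alone, and the count was 86 without SLE.yaa 2. Lyz2 had an adjusted p of 0.055 without WT 1 and 0.052 without WT 2, H2-M2 had 0.052 without SLE.yaa 2, and 29 of 44 genes named by the rule kept their calls with each mouse left out. C1qa lies on chromosome 4 (136895916 to 136898844).

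Genes of the distal X chromosome rose in B cells, CD4 and CD8 T cells and myeloid cells. The fixed list of 14 genes spans chromosome X, 166238943 to 169320374, the segment that Yaa moves to the Y chromosome. In B cells 8 of 9 listed genes rose, and 9 adjusted over the list alone, including Rab9 (0.87), Msl3 (0.79) and Trappc2 (0.76). Distal X genes had a median log2 change of 0.76 (camera adjusted p = 1.37e-16, or adjusted p = 0.174 with an estimated correlation). In CD4 T cells 9 of 9 rose, the same adjusted over the list alone, with Gpm6b far above the rest. Distal X genes had a median log2 change of 0.66 (camera adjusted p = 9.75e-06, or adjusted p = 0.184 with an estimated correlation). In CD8 T cells 1 of 8 rose, Tmsb4x (1.63), and 7 adjusted over the list alone. Distal X genes had a median log2 change of 0.58 (camera adjusted p = 2.93e-08, or adjusted p = 0.214 with an estimated correlation). In myeloid cells 5 of 10 rose, and 8 adjusted over the list alone, with Tmsb4x (1.22), Tlr8 (0.84, and 0.29 without DC) and Hccs (0.69). Distal X genes had a median log2 change of 0.63 (camera adjusted p = 8.92e-07, or adjusted p = 0.489 with an estimated correlation). Across all cells 8 of 10 rose, and 10 adjusted over the list alone. Distal X genes had a median log2 change of 0.71 (camera adjusted p = 1.25e-08, or adjusted p = 0.264 with an estimated correlation). Whether the change differed between cell types was not tested. The other genes of the X chromosome had medians of 0.02 in B cells, 0.02 in CD4 T cells and 0.02 in myeloid cells.

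**Figure D5:**
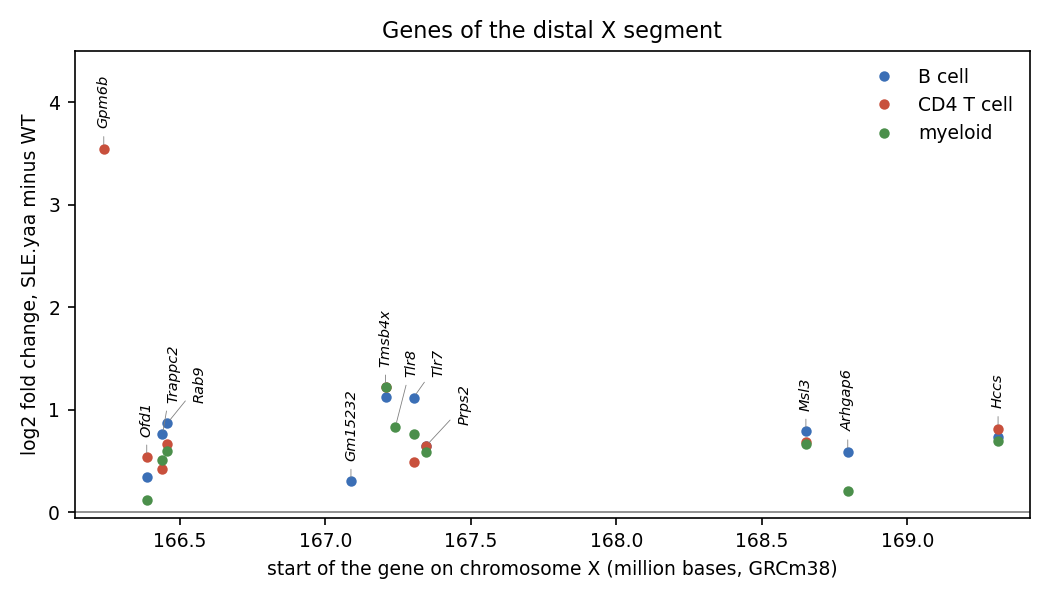
Log2 change of SLE.yaa against WT for genes of the distal X segment against their start on chromosome X in megabases (GRCm38), with 1 point per gene and comparison for B cells, CD4 T cells and myeloid cells. The points lie above 0, with Tlr7 at 1.12 in B cells and Gpm6b at 3.54 in CD4 T cells.

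In the remaining annotated types with at least 20 cells in each mouse, 1073 of 8832 genes passed in DC, 452 of 7889 in Mac, 115 of 6518 in neutrophils, 66 of 7611 in B-ISG, 33 of 7786 in early B cells and 7 of 8275 in NK cells (limma). The genes named here were chosen after their values were seen. In Mac alone, Fcgr2b (−2.09), F13a1 (−1.66), H2-Aa (−1.66), Ccr2 (−1.28) and Ly6c2 (−1.095) fell, and Pecam1 (2.63), Fpr1 (2.36), Cd300e (1.28), Nr4a1 (0.62) and Treml4 (0.56) rose. In DC, Fcgr4 (5.68), C1qb (4.81), Wfdc17 (4.51), Cd5l (3.47) and Hmox1 (2.55) rose, and the dendritic cell genes Flt3 (−1.85) and Cd209a (−1.81) fell. Without the DC that held 3 or more macrophage markers, a split by genes that rose, 56 genes passed, against 624 with as many DC drawn at random. H2-Aa then changed by −0.16 (adjusted p = 0.812), against −1.41 (adjusted p = 0.0104). In neutrophils the interferon-stimulated genes Ifi27l2a (2.26), Slfn4 (1.76) and Isg15 (1.63) rose. In B-ISG cells Iigp1 (3.86) and Socs3 (2.53) rose, while Ifit1 (−2.05), Rsad2 (−1.92) and Ifit3 (−1.67) fell. In NK cells Ifi27l2a (2.61), Ly6a (2.57), the T cell receptor component Cd3d (2.38) and Ltb (1.53) rose. Leaving out single mice changed these counts. B-ISG had 1 gene without WT 1 and 0 without WT 2 (limma, 368 at an unadjusted p under 0.05). Early B cells had 0 without SLE.yaa 1 (1070) and 0 without SLE.yaa 2 (1033), and neutrophils 0 without SLE.yaa 1 (689), 0 without SLE.yaa 2 (413) and 465 without WT 1. NK cells had 0 without SLE.yaa 1 (1265), 57 without SLE.yaa 2 and 11 without WT 1. DC had 2044 without WT 1, 2078 without WT 2, 522 without SLE.yaa 1 and 637 without SLE.yaa 2, and Mac 1644, 1031, 216 and 99 in the same order.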

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

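All tests in this part were chosen after the results they address had been seen, except the test of the difference between CD4 and CD8 T cells, whose named genes follow the rule fixed beforehand. No group had the 4 mice that a test for single unusual samples needs.

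Changes that differed between CD4 and CD8 T cells were found for 16 named genes (limma). They are given as the change in CD4 minus that in CD8, on log2 of vpm plus 10. Changes shifted toward a rise in CD4 T cells were Eea1 (2.73), Ramp1 (2.00), Lag3 (1.94), Bhlhe40 (1.75), Pdcd1 (1.498) and Tigit (1.36). Changes shifted the other way were Igfbp4 (−2.25), Satb1 (−1.76), Actn1 (−1.73), Ccl3 (−1.62), Gzmk (−1.58), Pde3b (−1.47), Gzmb (−1.43), Jchain (−1.39), Dapl1 (−1.22) and Lef1 (−0.99). Jchain was not higher in CD8 T cells once cells with a heavy chain were left out. It then averaged 0.198 and 0.101 depth-adjusted values per CD8 T cell of SLE.yaa 1 and SLE.yaa 2, against 0.282 and 0.115 per CD4 T cell. Ramp1 rose by 0.50 in CD4 T cells and had -1.499 in CD8 T cells.

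Data outside the comparisons also differed between the groups. Among IgM and IgD cells, 7.47% in SLE.yaa and 2.01% in WT had a difference from the V germline (exact permutation p = 0.333). Of the barcodes with a heavy chain, 25.9% in SLE.yaa and 9.54% in WT were outside the expression table, and of those with alpha and beta chains 24.7% and 11.3%. Of the heavy-chain cells outside the table, 51.3% and 46.3% were switched in SLE.yaa 1 and SLE.yaa 2, against 3.88% and 1.21% in WT 1 and WT 2.

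Macrophage genes rose in cells annotated DC of SLE.yaa mice. Free macrophage RNA is argued against, because C1qa in Mac of the same mice reached at most 0.411% of its level in DC. Deeper sequencing is argued against, because the C1qa mean was 26.1 times higher in SLE.yaa while the ratio of median UMI counts was 0.899. DC that took up macrophage genes and kept dendritic cell genes are argued against. In DC that held 3 or more macrophage markers, the median ratio of single dendritic cell markers to the other DC of the mouse was 0.0401 in SLE.yaa 1 and 0.188 in SLE.yaa 2. Of 14 markers with a ratio in both mice, 9 were under 0.333 in both, among them Flt3 and Cd209a at 0, and 3 were above 1 in both (Sirpa, Cadm1 and Itgax). The sum of MHC class II genes was at 0.247 and 0.216. Macrophages counted among these cells and DC that had lost dendritic cell genes cannot be told apart, since the sum of 16 markers, to which Sirpa adds most in the marked cells, was at 0.387 and 0.609, between the bounds set for it. These tests replaced one on the genes called after such a split, and whether strain or age underlies the pattern was not tested.

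Immunoglobulin transcripts rose in T, NK and myeloid cells of SLE.yaa mice. Free RNA from plasma cells may explain them, since among cells without a heavy chain the Ighg2c means of 6 types lay within 1.54-fold in SLE.yaa 1 and 2.28-fold in SLE.yaa 2, while plasma cells held 558 and 674 times the highest of them. The share of the difference left without heavy-chain cells tests droplets that also held a B-lineage cell. Of B-lineage cells, plasma cells among them, 17.6% in SLE.yaa 1 and 26.1% in SLE.yaa 2 had no heavy chain found, and these shares set the bounds. Of plasma cells alone it was 2.65% (1.22 to 4.97) and 2.79% (1.21 to 5.42). Those shares were not used, so droplets that held a plasma cell were judged by a looser bound. The median left was 98.6% for Ighg2c, 69.0% for Jchain and 57.2% for Igkc. Such droplets are argued against as the whole cause for Ighg2c outside CD4 T cells (at least 92.4% left) and for Igkc and Jchain in NK cells and DC (at least 85.1%). In SLE.yaa 2 they are also argued against for the 3 transcripts in CD4 T cells (at least 100.2%) and for Igkc and Jchain in Mac (at least 103%). For the 3 transcripts in CD4 T cells of SLE.yaa 1 the shares left met neither bound throughout (at most 48.8%), so the bounds gave no verdict. The same holds for Igkc and Jchain in CD8 T cells and neutrophils (at most 43.0%) and in Mac of SLE.yaa 1 (at most 29.3%). Most of the difference there lay in heavy-chain cells, as droplets would give. In CD8 T cells Igkc averaged 11.8 and 3.93 in SLE.yaa 1 and SLE.yaa 2, and 0.650 and 0.685 without heavy-chain cells. Without them, its means over the 6 types lay within 2.25-fold and 1.47-fold, as free RNA would give. Both may thus contribute, and the size of each part was not tested. The bounds and parts for this pattern and the next were revised after first bounds had given other verdicts.

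Genes of the distal X chromosome were higher in SLE.yaa. The other X genes had medians of at most 0.127 in either direction over 11 comparisons. TMM centres most genes near 0, so these medians alone could not show an error of scaling. Scaling between mice is argued against only for the gap between the segment and the other X genes, since it shifts all genes of a mouse alike. A candidate explanation is an additional copy of the segment, for which a median of at least 0.5, nearer to a doubling than to no change, was the bound. In the 10 comparisons other than DC the lowest median was 0.572. The pseudocount lowers these changes, and without it the medians of the 10 lay between 0.681 and 1.02. In DC, most of which held macrophage markers in SLE.yaa, the median was 0.417, so an additional copy and another cause cannot be told apart there. DC was set apart after the medians had been seen, and whether strain or age adds to the change was not tested.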

How the results depend on the processing

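Chosen after seeing the data were the fits without scaling or scaled to the sum alone, other scalings for lists, the pseudocounts, the blocks, other sets of annotated types, DC without macrophage markers, heavy-chain clones without plasma cells and clones by beta CDR3 alone; the rest were planned. No paired analysis was possible because the replicate numbers follow the order of the records; with them as a block, 334 genes passed over all cells, and with the numbers crossed 2213 did, and 850 in myeloid cells. Without scaling, 1539 genes passed over all cells and 1084 in B cells. With no filter on low values, 116 passed in B cells, 19 in CD8 T cells, 8 in myeloid cells and 625 in the other types, instead of 279, 261, 364 and 1746; more genes were then tested. In these cases the direction of most named genes held: planned settings kept 1237 calls of named genes and ended 126, leaving out 1 mouse kept 826 and ended 97, and added settings kept 1600, ended 44 and reversed 1. The reversed gene was C1qb in myeloid cells, at −0.0563 without DC, whose cells held most of it. Through every planned setting with all mice, 54 of 63 named genes kept their outcome over all cells. It was 24 of 45 in B cells and 70 of 73 in CD4 T cells. In CD8 T cells it was only 10 of 49, and in myeloid cells 5 of 44. The DC share changed by −0.0945 without DC that held macrophage markers, a filter that follows the change itself.

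Leaving out each mouse in turn, where the lone mouse of a group is assumed to vary like the other group, gave 457 to 1776 genes over all cells, 138 to 727 in B cells, 1398 to 2041 in CD4, 47 to 1752 in CD8, 86 to 546 in myeloid and 800 to 4205 in other types. It gave 1 to 4 cell types, 5 to 7 isotypes, 48 to 58 lists, 0 to 0 IGHV, 0 TRBV and 0 TRAV genes (edgeR, 3 to 8 IGHV genes at an unadjusted p under 0.05). The clonality differences were 6.31 to 9.83 percentage points for heavy chains, 22.8 to 27.1 for T cells, 20.6 to 25.7 for CD4 and 12.2 to 18.3 for CD8 T cells. The difference in the share of the largest CD4 clone ranged from −0.599 to 1.39 and reversed without WT 2 (−0.599) and without SLE.yaa 1 (−0.0503). Which property of a mouse moved these values was not tested.

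Of the list calls, 0 held with an estimated correlation and fry called 32, where the preset correlation gave 53. With 4 mice the estimated correlation left too few degrees of freedom to call lists, so this 0 decides nothing about them. With TMM over types 3 cell types passed, and without plasma cells, Mac, DC and neutrophils 0 did (edgeR, 1 at an unadjusted p under 0.05). IGHV8-8 alone, 1 gene, passed when cells were counted instead of clones, and 1 with TMM. The heavy-chain clonality difference was 11.5 with 85% CDR3 identity, 12.2 with the deposited clone identifier and 3.81 over barcodes in the expression table. It was 0.00311 over barcodes annotated B, B-ISG and B-early, which leaves out plasma cells and barcodes annotated as other types. There the largest clone share (−0.0543), inverse Simpson (9.85) and Gini index (−0.00046) reversed. Beyond the construction of each setting, the cause was not tested. A Wald test of DESeq2 was not run because the values are not counts, a doublet caller was not run without raw counts, other cluster resolutions were not run because no clusters were made here, and heavy with light chains were not run because heavy chains alone were used. Recovery in the simulation was lowest in NK cells, a type with few cells, where 15 of 100 genes changed 2-fold were recovered. The simulation did not separate depth from the number of cells.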

Other observations

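The tests in this part were all chosen after the results they address had been seen, and so were the values named.

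Among the IgM and IgD cells annotated B, IgD was called in 17.2% and 16.0% in WT 1 and WT 2 and in 34.3% and 42.6% in SLE.yaa 1 and SLE.yaa 2. IGHV8-8 made up 2.41% and 2.50% of the clones of cells annotated B, switched or not, in WT 1 and WT 2 and 3.62% and 4.55% in SLE.yaa 1 and SLE.yaa 2. Unswitched plasma cells of SLE.yaa 1 and SLE.yaa 2 had a V difference in 41.7% and 67.3%, against 2 of 10 and 1 of 10 in WT 1 and WT 2, and unswitched cells annotated B in 3.39% and 3.44%, against 1.94% and 1.88% in WT 1 and WT 2. Among switched cells the share with a V difference was 84.0% in WT, from 25 of 29 and 9 of 11 cells, and 72.6% in SLE.yaa, from 619 of 859 and 437 of 598 cells (exact permutation p = 0.333). The invariant chain TRAV11 with TRAJ18, which marks invariant NKT cells, was found in 5, 6, 5 and 2 cells of WT 1, WT 2, SLE.yaa 1 and SLE.yaa 2. In all 4 mice, 1 heavy CDR3 amino acid sequence and 0 beta sequences were found.

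Among barcodes in the expression table, the larger heavy-chain clones of SLE.yaa mice are consistent with expansion among plasma cells, since the difference between the groups was 3.81 percentage points with them and 0.00311 over cells annotated B, B-ISG and B-early. The clone members outside that table, 56.2% and 38.4% in SLE.yaa 1 and SLE.yaa 2, have no annotated type, so this does not extend to them. IGHG2C cells lay in clones at 34.6% and 29.2% in SLE.yaa 1 and SLE.yaa 2, and IGHM cells at 8.18% and 3.81%. Plasma cells hold many heavy-chain transcripts, so a role for free RNA in assigning barcodes to clones was not tested.

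The larger T cell clones may consist of cells that had met antigen. In CD4 T cells of SLE.yaa 1 and SLE.yaa 2, the sum of the naive genes in clone members was 0.514 and 0.565 times that in single cells. It was 0.703 times in WT 1, with 26 clone members, so this was not particular to SLE.yaa. For the activated and cytotoxic genes, the ratio in CD4 T cells was 2.07 in SLE.yaa 1, 1.15 in SLE.yaa 2 and 8.05 in WT 1. In CD8 T cells, the sum of the activated and cytotoxic genes in clone members was 2.50 and 1.94 times that in single cells. All these ratios are within a mouse, so differences between mice in depth do not enter them.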
